A study of Drosophila melanogaster with 6 samples.

How the data were processed

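RNA was measured by sequencing in 6 samples of the Drosophila salivary gland imaginal ring, 3 control and 3 NICD tumor, with groups taken from the sample titles and genotypes. Total RNA was extracted with a Zymo kit and made into libraries with Illumina protocols, per the labels' protocols. Reads were counted with featureCounts and compared with DESeq2 by the authors, per the submitters' processing notes, which give no versions. The aligner, genome build, annotation, strand setting, normalization factors and read filters are not given in the sources used here.

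The data analysed were a comparison table made by the authors and a sheet with numbers of calls. Per the file headers, the authors gave for each gene a log2 fold change, an unshrunk log2 fold change, a mean log2 CPM, a p-value and a false discovery rate. Printed folds and estimated CPM rest on the first of these, which the authors' deposited values give as a shrunken estimate, smaller in size than the unshrunk value in all 6113 genes that have both. The median difference was 0.00025 on the log2 scale, and the largest 0.60 (0.33 among the named genes). Those headers are the column names of edgeR's test against a minimum fold change, per the file headers, whereas the submitters' processing notes name DESeq2, and which tool the authors used for these values is not settled here. The authors' deposited call numbers stand under the headings "log 1.2" and "log 2", read here as minimum folds of 1.2 and 2, which the files do not spell out, and the contrast given there is tumor minus control. Counts of calls by the authors total 9384 tested genes, and the deposited gene rows number 6156, which equals the calls under heading 1.2 in both directions. The largest deposited adjusted p was 0.0499 and the smallest absolute log2 fold change 0.41. The authors' adjusted p equals the Benjamini-Hochberg value (p times tested genes over rank) within 1% for 98.7% of the genes. No row of a gene that was tested and not called was used here, so a member missing from the table was either not called or not tested.

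Because the files hold no value per sample, no test of single genes was run, and the plan fixed for this case was followed. It counts the authors' deposited adjusted p below 0.05. Total counts per library are unknown, so no counting interval or detection limit is given. How well the 3 samples of each group agree could not be examined. In 43 genes the authors' deposited unshrunk log2 fold change exceeds 100 in size, which marks a group fitted at 0 (40 in control, 3 in tumor), and no fold is printed for them. CPM per group was estimated from the authors' deposited mean log2 CPM and fold change, taking the mean CPM as the average of both groups. The estimates summed to 1224976 CPM in control and 351471 CPM in tumor over the listed genes, so by these estimates factors beyond library totals entered the values.

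A set of 26 gene lists with 809 symbols was fixed beforehand from textbook knowledge, including markers of fat body, hemocyte, muscle, neuron and glia, trachea, gut and cuticle. Of these symbols 788 were found in the table or the name tables, 19 were not found and 2 were second names of a gene already present. There were 514 list memberships in the table, from 502 distinct genes, and 274 members were not in the table. For each list the median log2 fold change was placed among 10000 random lists of the same size drawn from the listed genes, matched on mean log2 CPM in 20 bins. The two-sided p was adjusted by Benjamini-Hochberg over the 26 lists, and the smallest p these random lists can give is 0.0002. Such a p describes this table, since genes are not replicates, members of a list are correlated and all random genes are called genes. Counts adjusted over the list alone cannot be given, because the p-values of unlisted members were not used here.

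After the data were examined, random lists matched on transcript length as well (20 length bins, each with 5 expression bins) were added, with Fisher's exact test of direction and the share of members higher. Length is the median over annotated transcripts in the BDGP6 annotation (version 54, Ensembl release 115), known for 6111 of the listed genes (99.3%). That build may differ from the authors' build, so no coordinates are printed, and no genome sequence was used here, so GC content was not tested. Correlations across genes used 100000 permutations, or exact enumeration under 10 genes.

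Genes were named by a rule fixed in advance: N and all listed E(spl) members, the 10 largest rises and 10 largest falls above the lower quartile of mean log2 CPM (3.06), and up to 4 members per list with the smallest adjusted p. This gave 123 genes, and any other gene named is said to have been chosen after its value was seen. Other settings chosen before the data were examined and run were an adjusted p below 0.01, a 2-fold minimum, the quartile filter, unmatched random lists and the mean in place of the median.

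The list test was tested on simulated data, with 400 lists of 20 genes from the 6156 genes with length and expression trends built in and every other list drawn from short genes. With no shift, 13.2% of lists were called with expression matched and 4.75% with length matched as well, at an unadjusted p below 0.05. With a shift of 1 on the log2 scale these shares were 25.8% and 46.0%, and with a shift of 2 they were 77.5% and 93.2%. The simulated fold changes rose with mean expression, whereas those of the listed genes fell with it (Spearman's rho -0.355). These shares therefore describe the simulated setting and not error rates in this table. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.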

Results

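RNA sequencing was used to compare the salivary gland imaginal ring of Drosophila larvae between 3 control samples and 3 tumor samples. The imaginal ring is the small group of diploid progenitor cells at the neck of the larval salivary gland, whose secretory cells are large and polyploid. The tumors were made by overexpressing NICD, the intracellular domain of the receptor Notch, which acts with the DNA-binding protein Su(H) to switch on Notch target genes. Controls carried the same ubiquitous actin driver with GFP alone, and Gal80ts, a temperature-sensitive repressor of the driver, set when expression began. Controls were labelled as larvae of the last instar, and tumors were labelled with 7 days at 18 °C followed by 7 days at 29 °C. The labels give no days or temperatures for controls, so whether larval age and temperature differed along with genotype is not known, and no value here could separate them.

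The comparison asked which transcripts differ between NICD tumors and control imaginal rings. The values used are the authors' own comparison, which holds no value per sample, so the depth per library is unknown and no SD, SE or n accompanies a fold change. The labels do not say whether the 3 samples of a group came from separate animals or pools, so the authors' p-values measure the spread between these samples, which may be technical. Positive log2 fold changes mean higher in tumor, and CPM means counts per 1000000 reads averaged over all libraries. Where an estimated CPM of a single group is given, it rests on scaling factors that are not known, so it is not a share of the reads.

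Most tested genes differed. The authors' deposited table lists 6156 of 9384 tested genes (65.6%) at an adjusted p below 0.05, of which 3187 were higher and 2969 lower in tumor. Of the listed genes, 2502 were at least 2-fold higher and 2209 at least 2-fold lower, and 379 and 295 passed 16-fold in the same directions. Under a second heading of 2 in place of 1.2, the authors' deposited calls number 3550, of which 1845 were higher. The median log2 fold change of the listed genes was 0.57, so 109 genes listed as higher lie below that median.

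**Figure D1:**
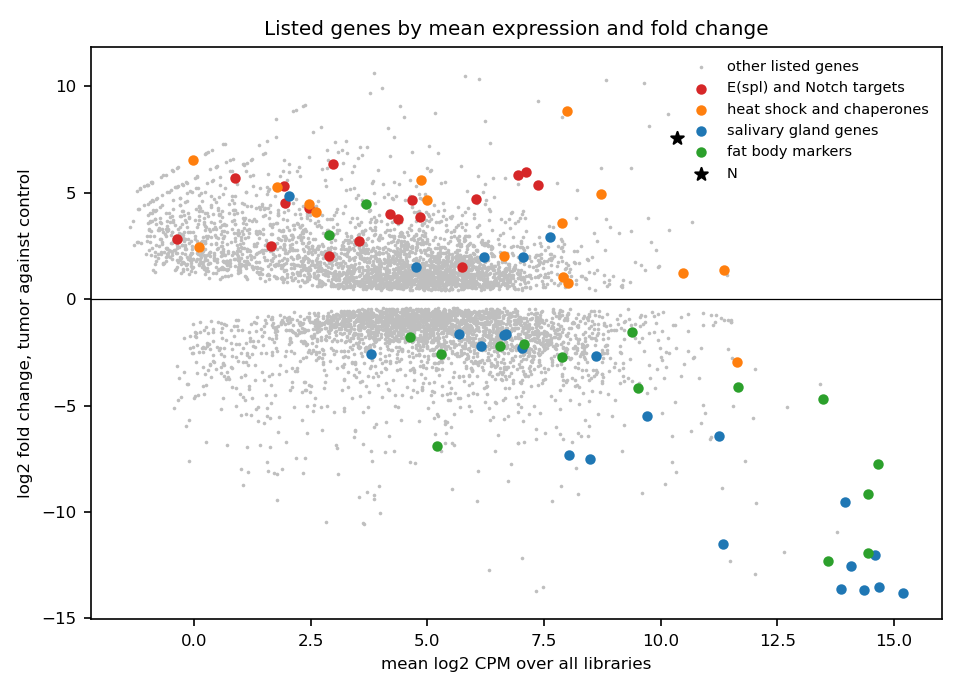
Each point is 1 of the 6156 listed genes except those fitted at 0 in one group, placed by mean log2 CPM (x axis) and log2 fold change of tumor against control (y axis), with 4 gene lists in color and N as a star. Salivary gland genes such as Sgs7 (log2 fold change -13.81) lie at the lower right, while N (7.56) and most E(spl) and Notch target genes lie above 0.

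Notch itself and its best-known target genes rose in tumor. By the authors' deposited table, N was 188-fold higher (log2 fold change 7.56, adjusted p = 1.07e-05, mean 1299 CPM), although reads from the NICD transgene can be counted under N. The E(spl) complex encodes basic helix-loop-helix repressors and Bearded-family proteins transcribed in response to Notch. Its members E(spl)m6-BFM, E(spl)m2-BFM and E(spl)m3-HLH were 82.2-fold, 62.3-fold and 57.2-fold higher in the authors' deposited table. E(spl)mbeta-HLH (40.8-fold), E(spl)malpha-BFM (25.6-fold), E(spl)m7-HLH (25.4-fold) and E(spl)m8-HLH (15.96-fold) followed in the authors' deposited table, with E(spl)m5-HLH (7.13-fold) and E(spl)mgamma-HLH (4.10-fold) lowest. Kaz-m1, the gene at the m1 position of the complex, is listed in the authors' deposited table at a fitted level of 0 in control, so no fold is given.

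Of the 21 genes fixed as E(spl) complex and direct Notch targets, 19 were listed and all 19 were higher, with a median log2 fold change of 4.51 (4.39 without the gene fitted at 0). E(spl)mdelta-HLH and E(spl)m4-BFM were not in the table, and whether they were tested and not called, or not tested, is unknown. The list lay above random lists of equal mean expression (adjusted p = 0.00065, the smallest that 10000 random lists over 26 lists gave) and of equal transcript length (adjusted p = 0.00074). The neural stem cell repressor gene dpn was 39.3-fold higher in the authors' deposited table. Of 16 listed Notch pathway components 14 were higher, with a median of 1.75 (adjusted p = 0.0075), but the call ended once transcript length was matched (adjusted p = 0.067). The ligand genes Dl and Ser were 12.3-fold and 10.4-fold higher, and numb, which encodes a Notch inhibitor, 3.93-fold higher, in the authors' deposited table.

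Salivary gland secretion genes held 5 of the 10 largest falls of single genes, while the larval cuticle list had the lowest median. Sgs7, Sgs5, Sgs8 and Sgs3, which encode glue proteins that fix the pupal case to its substrate, were 14339-fold, 13161-fold, 12628-fold and 11576-fold lower in the authors' deposited table. Eig71Ee, another secreted product of the late larval gland, was 5846-fold lower, and sage, a transcription factor gene of salivary gland secretory cells, was 45.4-fold lower in the authors' deposited table. Of 24 listed salivary gland genes, 19 were lower and 5 higher, with a median log2 fold change of -4.09, or -5.50 above the lower quartile of expression (adjusted p = 0.00065, and 0.00074 with transcript length matched). The size of the falls sets this call, since the share higher, 20.8%, did not pass the test against the 29.3% of random lists of equal length and expression (adjusted p = 0.51). The 5 higher members were CG13159 (28.3-fold), toe (7.54-fold), hth (3.90-fold), eyg (3.87-fold) and Scr (2.83-fold), named after their values in the authors' deposited table were seen. Estimated from the table, this list summed to 328764 CPM in control and 1202 CPM in tumor.

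Fat body transcripts were lower as well. Of 16 listed fat body markers 14 were lower, with a median of -3.43, or -4.12 above the lower quartile of expression (adjusted p = 0.0012, and 0.00074 with length matched). The larval storage protein genes Lsp1alpha and Lsp1beta were 3869-fold and 561-fold lower, Fbp2 was 5125-fold lower and the yolk protein gene Yp3 was 121-fold lower in the authors' deposited table. The estimated sum of these markers was 195659 CPM in control and 2166 CPM in tumor. Larval cuticle genes also fell, with 8 of 9 listed markers lower and a median of -5.92 (-6.44 without the gene fitted at 0; adjusted p = 0.00065, and 0.0028 with length matched). The size of these falls sets the call, since the share higher, 11.1%, did not pass against the 16.7% of random lists of equal length and expression. Lcp4, Lcp2, Lcp3 and Lcp65Ag1 were 558-fold, 368-fold, 299-fold and 124-fold lower in the authors' deposited table, and similar sequences in this family make single members uncertain. Of 25 listed genes whose symbols begin with Cpr, some also in the cuticle list, 15 were lower and 10 higher. That symbol group was chosen after the data were examined. Muscle markers were lower in 17 of 19 listed genes, with a median of -2.71 (adjusted p = 0.0031, and 0.0026 with length matched). TpnC47D and Mlp60A were 65.0-fold and 9.38-fold lower in the authors' deposited table, with Mef2 (3.47-fold) and Strn-Mlck (2.53-fold) less so.

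The other genes among the 10 largest falls in the authors' deposited table were CG42834 (log2 fold change -13.73), CG14332 (-13.53), CG31698 (-12.92) and CR44316 (-12.74). Among the 10 largest rises, the authors' deposited table holds the antimicrobial peptide genes Def (10.50), AttD (10.34) and Mtk (9.28), the Hox gene Ubx (10.15) and the cuticle protein gene Cpr64Ac (9.93). CR45045 (10.62), CG13748 (10.27) and CG14960 (9.66) also rose in the authors' deposited table. The cuticle protein gene Cpr47Ea and the hemocyte gene NimC4 are listed in the authors' deposited table at a fitted level of 0 in control, so no fold is given.

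Immune genes and hemocyte markers rose. Of 25 listed antimicrobial peptide and immune genes 19 were higher, with a median log2 fold change of 1.95 (adjusted p = 0.0012, and 0.00074 with length matched). Mtk was 622-fold higher, PGRP-LF 7.79-fold and the NF-kappaB gene Dif 4.77-fold higher, whereas the peptidoglycan recognition gene PGRP-SD was 14.6-fold lower in the authors' deposited table. Of 13 listed hemocyte markers, genes of the circulating blood cells, 12 were higher, with a median of 4.68 (4.58 without the gene fitted at 0, 5.40 above the lower quartile of expression; adjusted p = 0.00065, and 0.00074 with length matched). The prophenoloxidase genes PPO2 and PPO1 were 71.3-fold and 43.8-fold higher, the phagocytic receptor gene eater 42.7-fold and He 22.3-fold higher in the authors' deposited table. NimC2, the remaining hemocyte marker, had a log2 fold change of -3.03 in the authors' deposited table and was chosen for mention after its value was seen.

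Tracheal markers were higher in 10 of 10 listed genes, with a median of 2.65 (adjusted p = 0.0012, and 0.0019 with length matched). Breathless, the tracheal FGF receptor gene btl, was 17.1-fold higher and the tracheal transcription factor gene trh 8.63-fold higher in the authors' deposited table. The chitin synthase gene kkv (7.29-fold) and knk (8.54-fold), which acts in chitin organization, are also listed as higher in the authors' deposited table. Neuron and glia markers were higher in 8 of 10 listed genes, with a median of 1.59 that did not pass the test (adjusted p = 0.068, and 0.36 with length matched). The neuronal genes elav (4.41-fold) and futsch (4.97-fold) and the glial gene moody (4.96-fold) were higher, and Syt1 was 5.40-fold lower, in the authors' deposited table. Only 4 of 28 gut and proventriculus markers were listed, 2 in each direction (median -0.16, adjusted p = 0.52, and 0.57 with length matched). In the authors' deposited table Mal-A6 was 9.68-fold and Peritrophin-A 2.62-fold lower, and PGRP-SC2 4.58-fold and Mal-B1 2.09-fold higher.

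**Figure D2:**
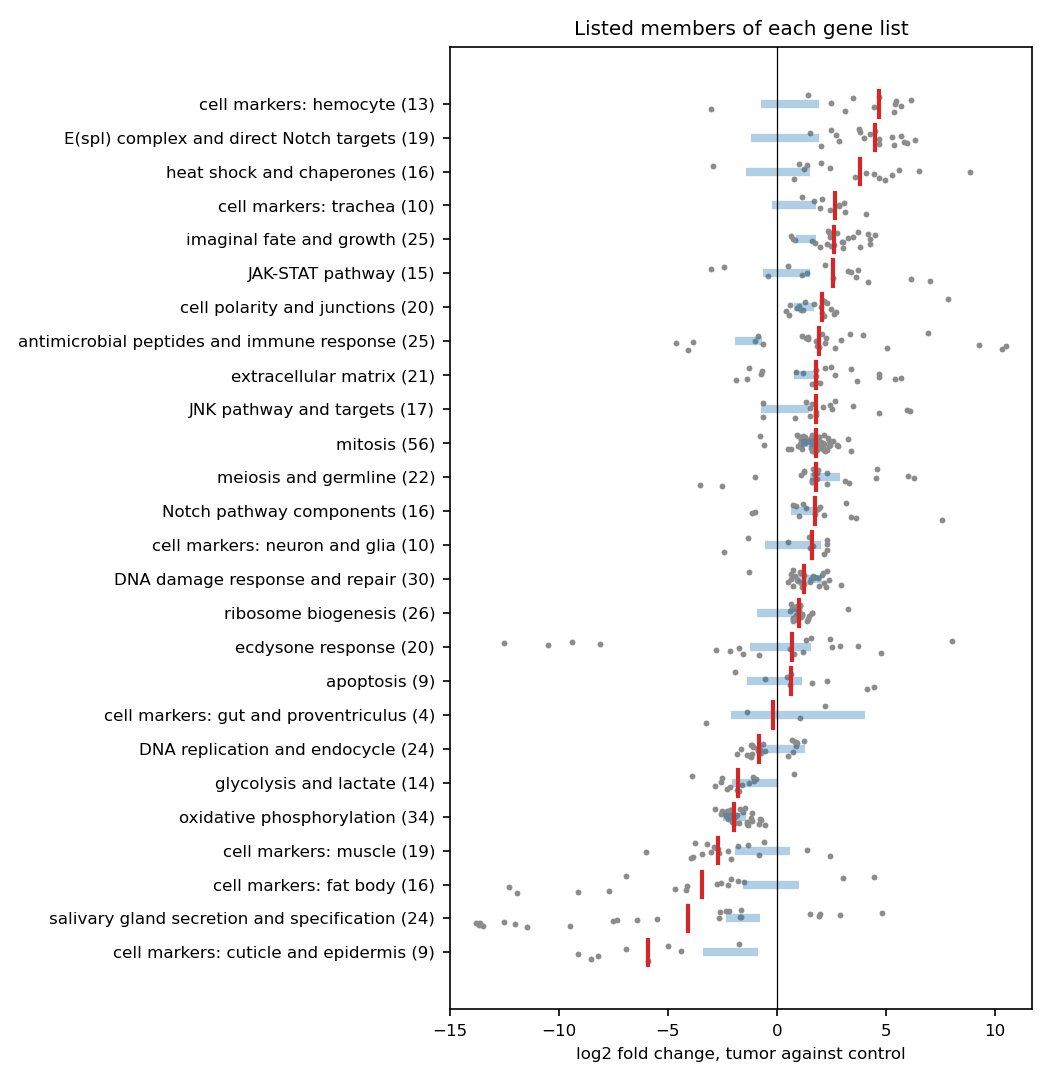
Grey points are listed members of each of 26 gene lists (number of listed members in brackets) by log2 fold change, red bars are list medians, and blue bars span the central 95% of medians of random lists matched on transcript length and mean expression. Genes fitted at 0 in one group have no point, and the medians run from -5.92 for cuticle markers to 4.68 for hemocyte markers.

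Genes of imaginal fate, growth and epithelial polarity rose. All 25 listed imaginal fate and growth genes were higher, with a median log2 fold change of 2.64 (adjusted p = 0.00065, and 0.00074 with length matched). The EGF receptor pathway genes rho and kek1 were 22.6-fold and 13.3-fold higher, the insulin receptor gene InR 11.2-fold and sd, which encodes the DNA-binding partner of Yorkie, 3.33-fold higher in the authors' deposited table. All 20 listed polarity and junction genes were also higher, with a median of 2.05 (adjusted p = 0.00065, and 0.0036 with length matched). The apical polarity genes baz and sdt were 6.53-fold and 4.26-fold higher in the authors' deposited table, as were the adhesion genes Fas3 (4.88-fold) and ed (4.18-fold).

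Genes of JNK and JAK-STAT signaling rose, and the call for matrix genes depended on transcript length. In the JNK list 15 of 17 listed genes were higher, with a median of 1.81 (adjusted p = 0.0012, and 0.0036 with length matched). Mmp1, a matrix metalloproteinase gene, was 25.4-fold higher, Traf4 11.3-fold, Gadd45 4.34-fold and the Fos gene kay 3.50-fold higher in the authors' deposited table. For JAK-STAT, 12 of 15 listed genes were higher, with a median of 2.59 (adjusted p = 0.0012, and 0.0023 with length matched). The share higher, 80%, did not pass against the 65.2% of random lists of equal length and expression (adjusted p = 0.30). The cytokine gene upd3 was 70.2-fold higher in the authors' deposited table, with zfh2 (13.2-fold), the feedback inhibitor gene Socs36E (12.2-fold) and chinmo (10.5-fold). The stress-induced genes TotA and TotC, chosen for mention after their values were seen, were 8.28-fold and 5.38-fold lower in the authors' deposited table, and the list's estimated sum was 2813 CPM in control and 1427 CPM in tumor, with TotA the most abundant member. Extracellular matrix genes were higher in 16 of 21 listed members, with a median of 1.81 (adjusted p = 0.0015), a call that ended with length matched (adjusted p = 0.051). The 5 lower members include trol (3.69-fold), SPARC (2.59-fold) and Tig (2.41-fold), named after their values in the authors' deposited table were seen. Mmp1, Mmp2 and Timp are in both the matrix and the JNK list, so these lists are not independent, and Mmp2 is the median member of both. Mmp2 and Timp were likewise named after their values were seen. Ppn (42.3-fold), the beta integrin gene Itgbn (10.4-fold) and the glypican gene dally (5.57-fold) were higher in the authors' deposited table, beside medians of 4.68 for the hemocyte list and 2.65 for the tracheal list.

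Heat shock genes rose in samples labelled with a 29 °C period. Of 16 listed heat shock and chaperone genes 15 were higher, with a median log2 fold change of 3.81 (adjusted p = 0.00065, and 0.00074 with length matched). Above the lower quartile of expression, which leaves out several Hsp70 copies, the median was 2.003 (adjusted p = 0.0012). Hsp70Bb was 462-fold higher in the authors' deposited table, although near-identical Hsp70 copies can share reads and make each copy uncertain. The small heat shock protein gene Hsp26 (30.8-fold) and stv (4.01-fold), a co-chaperone gene, were also higher, and the endoplasmic reticulum chaperone gene Hsc70-3 was 7.70-fold lower in the authors' deposited table.

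Mitotic genes were mostly higher and replication genes were divided. Of 56 listed mitosis genes 54 were higher, with a median log2 fold change of 1.78 (adjusted p = 0.00065). Long transcripts as a class were higher in tumor, and with transcript length matched the mitosis call ended (adjusted p = 0.090, where random lists had a median of 1.41). The share higher, 96.4%, still passed against the 83.2% of random lists of equal length and expression (adjusted p = 0.013). The centriole gene ana1 was 9.53-fold higher in the authors' deposited table, with the kinetochore genes Spc105R (7.08-fold) and cmet (5.21-fold) and the spindle gene mars (5.90-fold). Of 24 listed replication and endocycle genes 16 were lower and 8 higher. Their median of -0.81 and mean of -0.44 did not pass the test (adjusted p = 0.28 and 0.20, and 0.12 for the median with length matched). Among members with a known length 34.8% were higher, which passed against the 56.1% of random lists of equal length and expression (adjusted p = 0.031). Within this list fold change rose with transcript length (Spearman's rho 0.69). The origin-licensing gene Cdc6 was 3.60-fold lower and RnrS, a ribonucleotide reductase subunit gene, 2.26-fold lower, while Gnf1 and RpA-70 were 1.82-fold and 1.83-fold higher in the authors' deposited table.

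DNA damage response genes were higher in 29 of 30 listed members, but their median of 1.23 did not pass the test (adjusted p = 0.18, and 0.50 with length matched, where random lists had a median of 1.42). Their mean of 1.37 passed against lists matched on expression alone (adjusted p = 0.034). The share higher, 96.7%, passed against the 81.2% of random lists of equal length and expression (adjusted p = 0.028). The repair genes rad50 and Xpc were 5.26-fold and 4.49-fold higher, and the checkpoint kinase gene lok 3.79-fold higher, in the authors' deposited table. Meiosis and germline genes were higher in 19 of 22 listed members, with a median of 1.78 that did not pass (adjusted p = 0.83, and 0.46 with length matched). The germline gene piwi was 78.0-fold higher at a mean of 2.09 CPM, mei-P26 3.63-fold and nod 3.06-fold higher, and mei-P22 11.5-fold lower in the authors' deposited table. Apoptosis genes were higher in 7 of 9 listed members, with a median of 0.66 that did not pass (adjusted p = 0.83, and 0.33 with length matched). Neither their mean of 1.30 nor their median of 1.13 above the lower quartile of expression passed (adjusted p = 0.15 and 0.27). The death-inducing genes hid and rpr were 21.7-fold and 17.4-fold higher, the caspase gene Dronc 3.05-fold higher and Buffy 3.75-fold lower in the authors' deposited table.

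Energy metabolism genes were listed as lower almost throughout. All 34 listed oxidative phosphorylation genes were lower, with a median log2 fold change of -1.96, which did not pass against lists of equal expression (adjusted p = 0.068) or equal length (adjusted p = 0.96). ATPsyndelta was 4.98-fold, SdhD 4.78-fold, ATPsyngamma 4.42-fold and Cyt-c1 3.78-fold lower in the authors' deposited table. Of 14 listed glycolysis genes 13 were lower, with a median of -1.78 that did not pass (adjusted p = 0.53, and 0.27 with length matched). The fructose bisphosphatase gene fbp, whose product acts in the opposite direction to glycolysis, was 15.1-fold lower in the authors' deposited table, with Gapdh1 (7.29-fold), Pglym78 (6.01-fold) and Pgi (3.56-fold). All 26 listed ribosome biogenesis genes were higher, with a median of 1.01 that did not pass (adjusted p = 0.10, and 0.053 with length matched). Their mean of 1.10 passed against lists matched on expression alone (adjusted p = 0.016). The share higher, 100%, also passed against the 48.3% of random lists of equal length and expression (adjusted p = 0.0013). Non1 was 9.58-fold higher in the authors' deposited table, and RpI1 (3.05-fold), mbm (2.75-fold) and Nopp140 (2.72-fold) less so.

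Ecdysone response genes went both ways, with 11 of 20 listed members higher. Their median of 0.68 and mean of -0.996 differ in sign, and the test did not pass (adjusted p = 0.52, and 0.89 with length matched). The nuclear receptor gene ftz-f1 was 5.78-fold higher, while Eig71Ea was 1464-fold and Eip55E 7.00-fold lower in the authors' deposited table.

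Fold change rose with transcript length across the listed genes. Over 6111 genes with an annotated length, Spearman's rho was 0.45 and Pearson's r with log10 length was 0.37, across genes that are not independent replicates. In the decile with the shortest transcripts 20.8% of listed genes were higher in tumor (median log2 fold change -1.82), against 93.8% in the decile with the longest (median 1.68). Of the 26 lists, 16 passed an adjusted p of 0.05 against random lists matched on expression, and 13 with length matched as well.

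**Figure D3:**
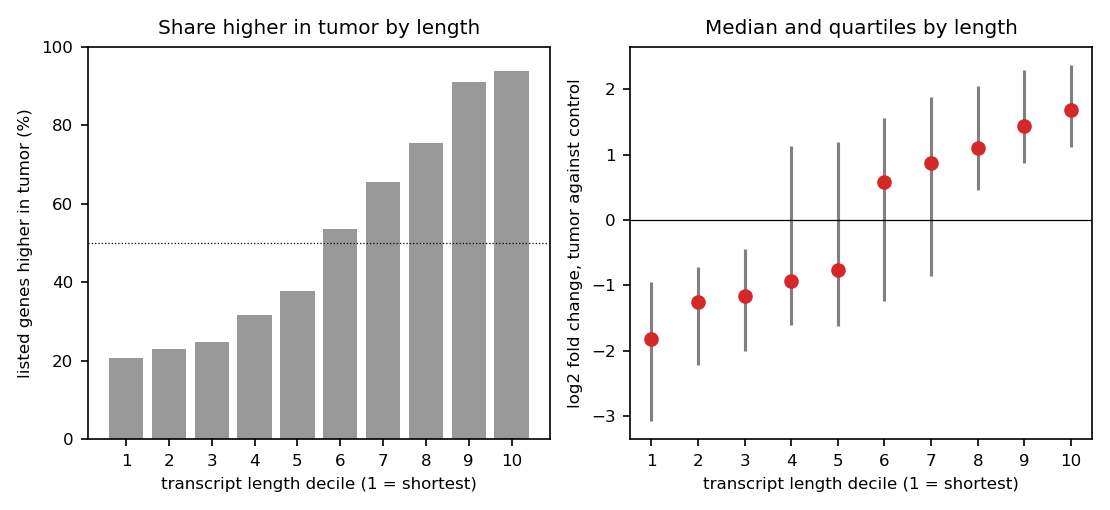
Listed genes were divided into 10 groups by median annotated transcript length (x axis, 1 is shortest), with the percent of genes higher in tumor as bars and the median log2 fold change as points, whose lines span the quartiles. The percent higher runs from 20.8 in the shortest group to 93.8 in the longest, and the dotted line marks equal numbers in both directions.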

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

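The alternatives with matched length, Fisher's test, share of members higher, genes fitted at 0 left out, the authors' second heading, and the stricter limits applied to named genes were chosen after the data were examined. The number of listed genes fell from 6156 to 3550 (1845 higher) under the authors' heading 2, a stricter call by construction, and stood at 4882 with an adjusted p below 0.01, 4711 with a 2-fold minimum and 4617 above the lower quartile of expression. Of those 4617 genes, 2092 were higher. The number of lists past the threshold was 16, and ranged from 13 with length matched to 21 with Fisher's test, with 19 unmatched, 18 by the mean and 14 by the share higher. With length matched, 3 lists lost their call (Notch pathway components, mitosis and extracellular matrix), and none of the 26 gained one. Matching on the longest transcript in place of the median gave 16: Notch pathway components stayed lost (adjusted p = 0.076), mitosis and extracellular matrix kept their call (0.028 and 0.020), and ribosome biogenesis gained one (0.028). The mean added DNA damage and ribosome biogenesis (adjusted p = 0.034 and 0.016), and unmatched lists added meiosis, glycolysis and oxidative phosphorylation. Fisher's test of direction added 5 lists (DNA damage, meiosis, glycolysis, oxidative phosphorylation and ribosome biogenesis). The share of members higher with length matched added 3 (replication, DNA damage and ribosome biogenesis) and lost 5 (Notch pathway, JAK-STAT, salivary gland, extracellular matrix and cuticle). The cause of these differences was not tested. Of the 123 named genes, 121 passed an adjusted p of 0.01 and 121 a 2-fold minimum. The gut list had too few genes left for the quartile filter.

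No paired analysis was possible because the files used hold no value per sample. For the same reason, leaving out single replicates, other splits of the samples, a second count model (edgeR and DESeq2 were both foreseen had there been counts), other size factors, other count filters, pseudocounts and an estimated correlation between genes were not run. What depth limits is unknown without counts, and a gene not called and a gene not tested look alike in the table.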

Other observations

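The tests of a length-dependent library difference, of the length trend with no limit on the fold, of scaling to library totals and of the fat body, muscle and hemocyte shares were chosen only after the results were seen, as were the gene groups in the next 2 paragraphs. For the 3 marker sets the full range of fold changes was tested first, and the interquartile range was added after those ranges were known, because single markers set some of them. By the full range alone, all 3 sets spread over more than 3 log2 units, the limit set for a common factor, and an explanation is argued against here only where both measures pass it.

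Several complexes had all listed members on 1 side of 0, and some genes here are shared with the fixed lists. All 56 listed mitochondrial ribosomal protein genes were lower in tumor (median log2 fold change -1.21), as were all 31 NADH dehydrogenase subunit genes (-2.05), 9 of them also in the oxidative phosphorylation list, and all 30 proteasome subunit genes (-1.74). Also lower were all 13 listed signal recognition particle and translocon genes (-2.67), all 7 coatomer genes (-2.05) and all 13 vacuolar ATPase genes (-1.11). None of these 6 medians lay outside random lists of the same length and expression (smallest adjusted p = 0.49). Of 32 gene families defined by symbol, 2 passed both Fisher's exact test and the length-matched test: 11 of 11 Hsp genes, which all belong to the heat shock list as well, were higher (median 4.67) and 15 of 18 odorant-binding protein genes were lower (median -3.24). Among 49 listed genes whose symbols begin with Cyp, mostly cytochrome P450 genes but with the cyclophilin gene Cyp1 and a pseudogene among them, 31 were lower and 18 higher (median -1.56, length-matched adjusted p = 0.0032), but their direction did not pass Fisher's exact test (adjusted p = 0.077). The symbol groups alpha (median -1.21), yellow (-2.12) and Spn (1.12) likewise passed the length-matched test alone (adjusted p = 0.048 each).

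Hox genes moved apart. Ubx, which specifies posterior thoracic and abdominal segments, had a log2 fold change of 10.15 in the authors' deposited table (adjusted p = 1.44e-05), with an estimated 1.40 CPM in control and 1595 CPM in tumor. Scr, the Hox gene that specifies the salivary gland, was 2.83-fold higher in the authors' deposited table (adjusted p = 0.0027), pb 4.36-fold higher (0.028) and Antp 2.66-fold lower (0.010). Whether the Ubx reads come from the endogenous gene or from a transgene was not tested.

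Fold change rose with transcript length over the listed genes (rho 0.45). Without a set of mitochondrial, proteasome, secretory and other-tissue genes, rho was 0.43 (bootstrap 95% interval 0.413 to 0.454) over 5793 of the 6111 genes. Without changes of 16-fold or more as well, rho was 0.50 (0.478 to 0.523) over 5162 genes. These intervals resample genes, which are not independent replicates, and do not measure variation between samples. The values argue against the fall of the genes left out as the whole cause of the trend. Other genes of the same tissues may have stayed in, so a smaller share of secretory or other tissue stays open for the trend, untested. A difference in mean expression is argued against by a rank correlation of 0.51 at fixed expression. A length-dependent difference between the libraries, such as RNA integrity or fragment selection, stays open. Fold change rose with length within 6 of 6 groups of complex subunits chosen by symbol (rho 0.54 to 0.96, largest adjusted p = 0.021 by permutation). The signal recognition particle and translocon group pools more than 1 complex, and separate regulation of members was not excluded in any group. Within the fixed lists the trend was less uniform. Of 23 lists with 10 or more genes, 16 had a rho above 0, and the lowest was -0.52 for antimicrobial peptide and immune genes. A biological difference between tumor and control that follows transcript length, or any difference of age or temperature, was not tested and also stays open.

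Salivary secretion, fat body and muscle transcripts were lower in tumor. The estimated control CPM sum to 1224976 over the listed genes, which is above 1000000 and points to further scaling factors, but this sum does not bear on why these transcripts were lower. A scaling factor shifts all genes alike, and the list medians were -4.09, -3.43 and -2.71, against 4.68 for hemocyte markers. All 26 list medians kept their direction with fold changes centred on the median of the listed genes. This check was chosen after the data were examined. That median is 0.57, so centring could only lower the 3 negative list medians, and their kept direction does not bear on scaling. The differences between the list medians argue against scaling as the whole cause of the falls in these 3 lists. An effect of scaling on the size of the falls stays open. A smaller share of fat body of unchanged makeup is argued against only if no other cells expressed its markers, which was not tested. The 6 most abundant markers fell by amounts that spread over 8.20 log2 units (interquartile range 5.77), where 1 common factor would move them alike. Fbp1 and apolpp, named after their values were seen, stayed at an estimated 854 and 348 CPM in tumor, against 11.4 for Lsp1alpha and 4.81 for Fbp2. Expression in other cells would give such a spread too. A share that changed together with a stage-dependent change in fat body genes may also account for that spread. For muscle a smaller share cannot be told apart from regulation, since the 6 most abundant markers spread over 3.27 log2 units but have an interquartile range of 1.70, and Argk and Tm1, still at an estimated 723 and 540 CPM in tumor, set the upper end (both named after their values were seen). For salivary secretion genes no test of tissue share was made, so a smaller share of secretory cells stays open, untested. NICD expression and any difference in larval age or temperature stay open for all 3 groups, untested.

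Hemocyte transcripts were higher in tumor. The 6 most abundant markers spread over 9.18 log2 units, which rests on NimC2 alone (-3.03), and their interquartile range was 0.78. More hemocytes of unchanged makeup therefore cannot be told apart from other causes: 5 of the markers go with it and NimC2, at an estimated 223 CPM in control, goes against it. Immune activation in tumor tissue and any difference in larval age or temperature stay open, untested.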
